A study of Mus musculus with 9 samples.

How the data were processed

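RNA of primary mouse macrophages, cultured for 48 h on cp titanium (cpTi), on the metallic glass Zr61Cu25Al14 (Ta0) or on the metallic glass Zr58Cu25Al14Ta3 (Ta3), was sequenced in 3 libraries per material. Per the labels, polyA RNA was isolated with TRIzol and made into libraries with a NEBNext Ultra kit, and the genotype was wild type. The labels also name the tissue as a xenograft, a word that was not used for grouping.

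The authors deposited a single table of FPKM for 54532 genes and 9 libraries. Per the labels, the authors used CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the mouse build GRCm38 (mm10), with no role or order given for each tool and no strand setting. The columns carry short stems. The stem for titanium was read as cpTi, the one for tantalum as Ta3, the only material with tantalum, and the one for zirconium as Ta0. This reading rests on composition, and if the glasses were reversed, the Ta0 and Ta3 results would swap.

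In each library, the deposited FPKM multiplied by gene length were whole multiples of a single step, which gives back whole reads. All values (100%) were whole within 0.05 reads, and the rebuilt totals ran from 15517877 to 18689963 reads. The library scale behind the FPKM ran from 9078170 to 21911078 reads and stayed within 3.30% of proportional to median-ratio size factors, so the deposited FPKM carry that scaling and not a plain division by total reads. Gene positions were checked against GENCODE M21, where 54495 of the gene IDs (99.9%) were found and 53585 had the same position. The table holds 11 symbols turned into dates by a spreadsheet, and those genes are identified by their Ensembl IDs.

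Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which left 10858. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, as 3 group means in a single model, with a mean-variance trend and two-sided moderated tests. The p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were Ta0 against cpTi, Ta3 against cpTi and Ta3 against Ta0, and the genes called in the same direction against cpTi were counted. The shared cpTi libraries tie those comparisons together, so the overlap was set beside 100 simulations of unchanged groups against the same libraries.

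The model, the filter, the threshold, the lists, the rule for named genes and most of the other settings were fixed before the data were examined. In all 24 gene lists and 10 lists of cell type markers were written, and the 27 lists with at least 5 tested members were tested with camera in limma. They were inflammatory cytokines and mediators, alternative activation, type I interferon response, MHC class II and class I presentation, metallothioneins and copper or zinc handling, NRF2 antioxidant response, heat shock response, unfolded protein and integrated stress response, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, LXR targets and lipid storage, cell cycle, p53 targets and apoptosis, immediate early genes, osteoclast genes, secreted osteogenic and angiogenic factors, lysosome and phagocytosis, integrins and actin cytoskeleton, iron handling, matrix proteases and inhibitors, ribosomal proteins, mitochondrially encoded genes, and macrophage, monocyte and fibroblast markers. Camera used a preset correlation between genes of 0.01, with adjustment over the 81 tests of all lists and comparisons. It was repeated with an estimated correlation. The list test fry in limma was run beside it with the same adjustment, but list calls are those of camera. Members were also counted with p-values adjusted over the list alone. The dendritic cell, neutrophil, mast cell, endothelial, T and NK cell, B cell and erythroid markers had fewer than 5 tested members.

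Named genes followed a rule with 3 parts. The first part took, in each comparison and direction, the 5 called genes with the largest log2 fold change that were protein coding, had a gene name other than a clone or model number, had groups that did not overlap, and reached a mean of 5 FPKM in the higher group. The second part took from each list called by camera, or with at least 5 called members, the called members with the smallest adjusted p, up to 2 in each direction. The third part was a fixed set given whatever its p, namely Tnf, Il1b, Il6, Nos2, Cd86, Arg1, Mrc1, Il10, Tgfb1, Mt1, Mt2, Hmox1, Slc30a1, Bmp2, Osm, Vegfa, Acp5 and Spp1. Other genes named were chosen after their values were seen.

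Single measures of the libraries, such as the percent of reads in ribosomal protein genes, were compared by exact two-sided permutation tests, where 0.1 is the smallest p that 3 against 3 allows. The fit was tested on simulated data drawn from these libraries in 40 runs. For each glass against cpTi, 66, 67 and 67 genes were changed by 1, 2 and 3 on the log2 scale. The fit called 33.3%, 76.3% and 89.5% of them for Ta0 against cpTi, and 30.5%, 77.1% and 88.3% for Ta3 against cpTi. These shares depend on how many genes change. In 40 runs with unchanged groups, a gene was called in 0 runs for Ta0 against cpTi, 5 for Ta3 against cpTi and 3 for Ta3 against Ta0. Up to 6045 genes were called in such a run. Libraries were shuffled over all groups, so these counts are draws at a single rate and not a separate rate for each comparison. Each library was drawn once per run, a scheme chosen after a first version that drew libraries with replacement had been seen.

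The settings fixed beforehand changed the pseudocount to 0.1, the filter to none or to 5 FPKM, the scaling to median-ratio size factors, to quantiles, to a common FPKM total, or to that total without mitochondrial, ribosomal protein and the 20 highest genes, the threshold to an adjusted p of 0.01 or an added log2 fold change of 1, and the genes to protein coding ones. Others dropped the mean-variance trend, used sample quality weights or a block by replicate number, fitted only the 6 libraries compared, or left out each library in turn. After the data were seen, 6 more were added. They were the slope on gene length as a covariate, a lowess correction for gene length with a span of 0.3, the same with GC content, rebuilt reads with voom weights, FPKM scaled by the sum of all rebuilt reads, and 7 libraries without the 2 that had few single-read genes. Reads shared between near-identical genes cannot be separated in this table, and neither can antisense partners. Examples are Ifit3 and its close copy, H2-Q genes, and the pseudogenes of ribosomal proteins, Gapdh and Fth1. Any reads shared by the related genes Mt1 and Mt2, or Fpr1 and Fpr2, were not examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.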

Results

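RNA was measured in macrophages grown from mouse bone marrow, the phagocytes of the innate immune system, after 48 h of culture on implant materials. The materials were cp titanium (cpTi), a metallic glass of zirconium, copper and aluminium (Zr61Cu25Al14, here Ta0) and a glass that also holds tantalum (Zr58Cu25Al14Ta3, here Ta3). A metallic glass is an alloy without a crystal lattice. Each material had 3 libraries, 9 in all. No library came from another surface, so a fall on a glass cannot be told apart from a rise on cpTi. Read counts rebuilt from the deposited FPKM (fragments per kilobase of gene length, scaled by library) came to between 15517877 and 18689963 per library, and 10858 of 54532 genes passed the expression filter. The columns of the deposited table were tied to the glasses by their composition, so a reversed reading would swap the Ta0 and Ta3 results. Levels are given as mean FPKM ± SD with n = 3 libraries per group. Log2 fold changes are on the log2(FPKM + 1) scale with their SE, a scale that understates the change of low genes. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

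The libraries differed from each other along a direction that also set libraries of the same material apart. The first principal component held 72.0% of the variance. Ribosomal protein genes took 18.5% of the reads of Ta0 replicate 1 and 17.1% of those of Ta3 replicate 3, but 3.70% in cpTi replicate 3 and 2.29% in Ta3 replicate 2. The slope of a library's deviations on log2 gene length was -0.23 in Ta0 replicate 1 and -0.21 in Ta3 replicate 3, against 0.21 in cpTi replicate 3 and 0.27 in Ta3 replicate 2. Ta0 replicate 1 and Ta3 replicate 3 also had few genes with a single read, 9.77% and 7.89% of the genes with 1 to 20 reads, where the other libraries had 22.4% to 27.9%. They had 15678 and 13466 genes above 0 FPKM, where the other libraries had 18156 to 20635. The mean ribosomal protein share was 5.52 ± 1.93% on cpTi, 12.1 ± 5.78% on Ta0 and 9.74 ± 7.39% on Ta3 (n = 3). The exact two-sided permutation p for Ta0 against cpTi was 0.2, where 0.1 is the smallest that 3 against 3 allows. A partial link between this direction and the material is therefore not excluded.

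**Figure D1:**
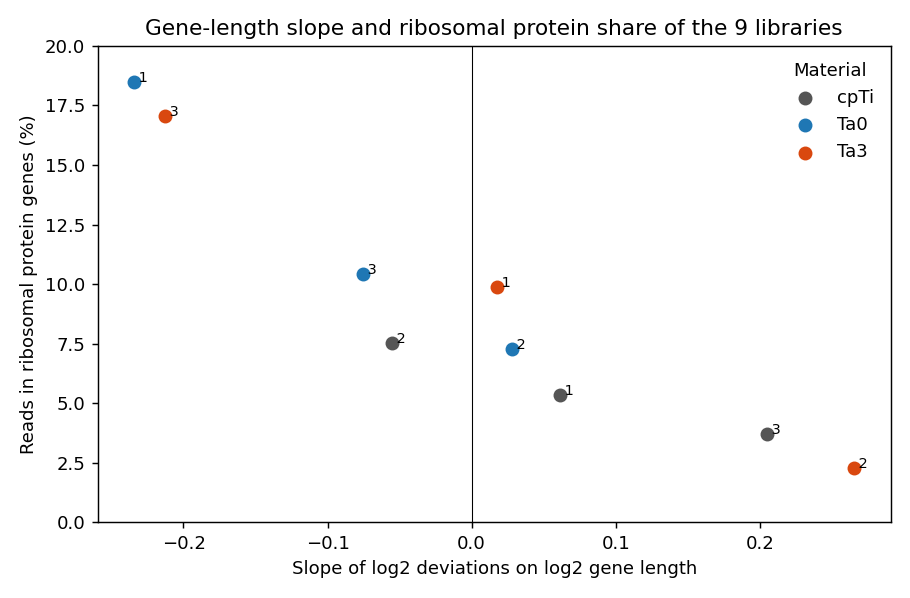
Each point is a library, with the slope of its log2 deviations on log2 gene length on the x axis and the percent of reads in ribosomal protein genes on the y axis. The share is highest, 18.5%, in Ta0 replicate 1, whose slope is -0.23, and lowest, 2.29%, in Ta3 replicate 2, whose slope is 0.27.

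The first comparison asked how macrophages on the tantalum-free glass differed from those on titanium. On Ta0, Acod1, whose product makes the antimicrobial metabolite itaconate, fell from 89.8 ± 14.9 FPKM on cpTi to 9.53 ± 2.60 on Ta0, a 9.42-fold difference. Cxcl2 and Cxcl3, chemokines that attract neutrophils, fell from 31.6 ± 5.63 to 3.11 ± 0.896 FPKM and from 23.5 ± 6.65 to 0.692 ± 0.327 FPKM. Il1b, the interleukin 1 beta gene, fell from 12.1 ± 3.45 to 1.13 ± 0.194 FPKM, and Tnf, the tumour necrosis factor gene, from 29.6 ± 4.48 to 9.25 ± 0.924 FPKM. Nos2, the inducible nitric oxide synthase, fell from 2.36 ± 0.193 to 0.109 ± 0.0577 FPKM. Fpr1 and Fpr2, receptors for bacterial formyl peptides, fell 8.32-fold and 9.45-fold, to 11.5 ± 3.32 and 16.6 ± 7.74 FPKM.

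Fewer genes rose on Ta0. Cdkn1c, a cyclin-dependent kinase inhibitor, rose from 5.32 ± 1.09 to 21.3 ± 6.27 FPKM. Cd5l, a secreted macrophage protein, rose from 11.8 ± 0.552 to 32.1 ± 4.30 FPKM, and Lsp1, an actin-binding leukocyte protein, from 17.6 ± 3.80 to 45.2 ± 4.51 FPKM. Matk, a kinase that restrains Src family kinases, rose 2.57-fold to 12.3 ± 1.91 FPKM. Pparg, a nuclear receptor that controls lipid genes, rose 1.95-fold to 23.4 ± 0.268 FPKM. In all, limma called 46 genes, 5 higher and 41 lower, and these 5 are all the genes that rose. For each gene named here as changed, the 3 Ta0 libraries lay outside the range of the cpTi libraries. The rule for the largest changes required this of the genes it picked, so for them it is no added evidence. The largest falls were Cxcl3 (log2 fold change -3.84 ± 0.30, adjusted p = 0.00252), Fpr2 (-3.15 ± 0.50, adjusted p = 0.0470) and Acod1 (-3.12 ± 0.21, adjusted p = 0.00252). The rises ran from Cdkn1c (1.8 ± 0.23, adjusted p = 0.0199) to Pparg (0.91 ± 0.14, adjusted p = 0.0437). On GRCm38, Acod1 (ENSMUSG00000022126) spans 103046977 to 103056573 of chromosome 14 and Cdkn1c (ENSMUSG00000037664) spans 143458339 to 143461050 of chromosome 7. Cxcl3 (ENSMUSG00000029379, 90786103 to 90789600) and Cxcl2 (ENSMUSG00000058427, 90903871 to 90905938) lie close together on chromosome 5, and Fpr1 (ENSMUSG00000045551, 17876471 to 17883940) and Fpr2 (ENSMUSG00000052270, 17887824 to 17893952) are neighbours on chromosome 17.

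Leaving out 1 library gave 9, 12 and 13 genes without cpTi replicates 1, 2 and 3, 10, 7 and 10 without Ta0 replicates 1, 2 and 3, and 13, 34 and 84 without Ta3 replicates 1, 2 and 3, with all 46 genes keeping their sign. Acod1, Cxcl2, Cxcl3, Il1b and Nos2 passed in each of these fits, Slc7a11 was lost without Ta0 replicate 2 (adjusted p = 0.0514), Rsad2 without cpTi replicate 1 or Ta0 replicate 1 or 2, Tnf without cpTi replicate 1 or 2 or any Ta0 library, and Cdkn1c, Cd5l, Lsp1, Matk, Pparg, Fpr1, Fpr2, Ifit2 and Slc25a37 without any 1 cpTi library, any Ta0 library (Ifit2 passed without Ta0 replicate 3) or Ta3 replicate 1, with Lsp1, Pparg and Fpr2 also lost without Ta3 replicate 2 and Fpr2 without Ta3 replicate 3 (adjusted p up to 0.274). With each library rescaled to a common FPKM total, where the median of all genes was -0.53, 11 genes passed, all lower, and Cdkn1c, Cd5l, Lsp1, Matk, Pparg, Rsad2, Ifit2, Slc7a11, Slc25a37 and Tnf did not.

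By gene group, the type I interferon response was lower on Ta0. Of its 21 tested members 2 fell, Rsad2 and Ifit2, and 14 fell when adjusted over the list alone. Rsad2, an antiviral enzyme, went from 13.6 ± 0.179 to 4.66 ± 0.517 FPKM and Ifit2, an antiviral RNA-binding protein, from 11.9 ± 0.655 to 3.62 ± 1.29 FPKM. The list's median log2 fold change was -0.99, with 20 of 21 members below 0 (camera adjusted p = 1.1e-18, and adjusted p = 0.0129 with an estimated correlation). Of the 20 tested inflammatory cytokines and mediators 5 fell, namely Tnf, Il1b, Cxcl2, Cxcl3 and Nos2, and 10 fell when adjusted over the list alone, among them Nfkbia, Il1a, Cxcl1, Ptgs2 and Tnfaip3. Their median was -0.63 (camera adjusted p = 1.3e-12, and adjusted p = 0.150 with an estimated correlation).

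Among antioxidant and iron genes, 1 of 19 NRF2 targets fell, Slc7a11, the cystine transporter subunit, from 5.47 ± 0.316 to 1.10 ± 0.124 FPKM. Adjusted over the list alone 3 fell, with Gclm and Gsr beside it. Of 14 iron handling genes Slc25a37, the mitochondrial iron importer, fell from 10.3 ± 0.740 to 3.24 ± 0.534 FPKM, and 3 fell when adjusted over the list alone, with Slc11a2 and Fbxl5. The medians were -0.27 and -0.26 (camera adjusted p = 0.00208 and 0.00186, and adjusted p = 0.464 and 0.148 with an estimated correlation). No MHC class I gene passed over all genes, and 4 of 15 fell when adjusted over the list alone (H2-Q4, H2-Q6, Tap1 and Nlrc5). That list had a median of -0.33 and a camera adjusted p of 0.00649, with adjusted p = 0.541 with an estimated correlation, and its call ended without cpTi replicate 2 (median -0.16, adjusted p = 0.103). H2-Q4 and H2-Q6 are close relatives that can share reads.

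Ribosomal protein and oxidative phosphorylation genes were shifted up as groups on Ta0, with 0 of 25 members past the limma test in either list. Their medians were 1.38 and 0.72, with 25 and 24 of 25 members above 0 (camera adjusted p = 9.0e-07 and 0.000219, and adjusted p = 0.698 and 0.733 with an estimated correlation). These medians were 0.81 and 0.36 without Ta0 replicate 1, the library with the highest ribosomal protein share, and 0.18 and 0.01 with the length slope as a covariate, where the call of oxidative phosphorylation ended (adjusted p = 0.708). MHC class II genes had a median of 0.44 with 0 of 7 members past the test (camera adjusted p = 0.0374, and adjusted p = 0.546 with an estimated correlation). That call was lost without cpTi replicate 1 or 2 or Ta0 replicate 1 or 2, and the median was -0.17 when each library was rescaled to a common FPKM total. In 40 simulations of unchanged groups from these libraries, camera with the preset correlation called a mean of 2.85 of 27 lists for this comparison, the ribosomal list in 30 runs and the inflammatory list in 7, and with an estimated correlation it called 0. The interferon calls of both glasses against cpTi are the only list calls that hold with an estimated correlation.

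**Figure D2:**
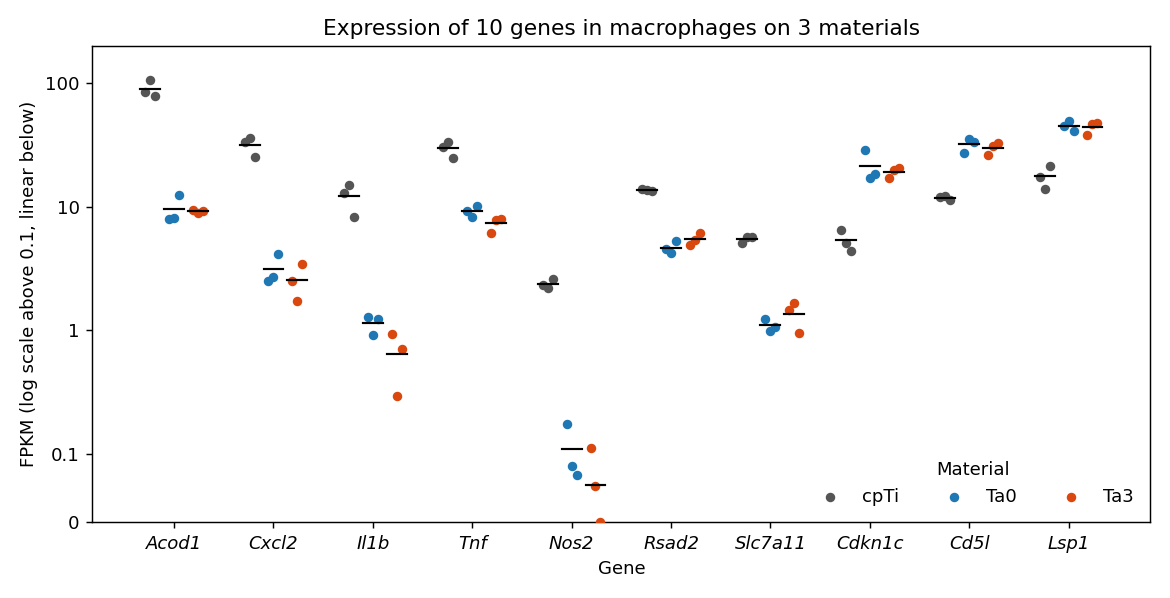
Points are the FPKM of single libraries for 10 genes on cpTi, Ta0 and Ta3, with 3 libraries per material, bars at the means and an axis that is logarithmic above 0.1 FPKM and linear below. Acod1 averages 89.8 FPKM on cpTi, 9.53 on Ta0 and 9.16 on Ta3, and Cdkn1c 5.32, 21.3 and 19.2 FPKM.

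The comparison of the tantalum-containing glass with titanium showed falls in many of the genes named above. Acod1 fell to 9.16 ± 0.288 FPKM, 9.80-fold below cpTi, Cxcl2 to 2.54 ± 0.845, Cxcl3 to 1.07 ± 0.770, Il1b to 0.642 ± 0.326, Tnf to 7.32 ± 1.03 and Nos2 to 0.0543 ± 0.0552 FPKM. Fpr2 fell from 157 ± 79.9 to 5.58 ± 2.24 FPKM and Fpr1 from 95.9 ± 41.7 to 6.43 ± 3.91 FPKM. Ifit3, an antiviral protein of the Ifit family whose reads can be shared with a close copy, fell from 22.9 ± 7.08 to 4.85 ± 1.17 FPKM. The genes that rose were Cdkn1c, to 19.2 ± 1.82 FPKM, Cd5l, to 30.0 ± 3.47 FPKM, and Lsp1, to 44.2 ± 5.45 FPKM.

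In this comparison limma called 52 genes, 3 higher and 49 lower. The largest falls were Fpr2 (log2 fold change -4.51 ± 0.50, adjusted p = 0.0118), Fpr1 (-3.75 ± 0.46, adjusted p = 0.0180) and Cxcl3 (-3.60 ± 0.30, adjusted p = 0.00252), and the largest rise was Cdkn1c (1.68 ± 0.23, adjusted p = 0.0281). Il1b (ENSMUSG00000027398) lies at 129364570 to 129371139 of chromosome 2, Tnf (ENSMUSG00000024401) at 35199381 to 35202007 of chromosome 17 and Nos2 (ENSMUSG00000020826) at 78920787 to 78960254 of chromosome 11. Without cpTi replicates 1, 2 and 3 the counts were 8, 10 and 22 genes, without Ta0 replicates 1, 2 and 3 they were 24, 15 and 19, and without Ta3 replicates 1, 2 and 3 they were 9, 23 and 30, with all 52 genes keeping their sign. Acod1, Cxcl2, Cxcl3, Il1b and Nos2 passed in each of these fits, Tnf was lost without cpTi replicate 1 (adjusted p = 0.0534), Fpr1, Fpr2 and Slc7a11 without cpTi replicate 1 or 2 or Ta3 replicate 1, Rsad2 without any 1 cpTi library or Ta3 replicate 1, Ifit3 without cpTi replicate 1 or 2, Ta0 replicate 2 or Ta3 replicate 1 or 2, and Cdkn1c, Cd5l, Lsp1 and Slc25a37 without any 1 cpTi or Ta3 library or Ta0 replicate 2 or 3, with Lsp1 and Slc25a37 also lost without Ta0 replicate 1 (adjusted p up to 0.293). With each library rescaled to a common FPKM total, where the median of all genes was -0.11, 9 genes passed, all lower. Cdkn1c, Cd5l, Lsp1, Rsad2, Ifit3, Slc7a11, Slc25a37 and Tnf did not pass there. With only the 6 libraries compared 7 genes passed, all lower, so Cdkn1c, Cd5l and Lsp1 were lost. With the length slope as a covariate 198 genes were higher and 385 lower.

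The type I interferon response was lower on Ta3 as well, with all 21 tested members below 0. Rsad2, Ifit3, Ifit2 and Cmpk2 fell, and 15 members fell when adjusted over the list alone. Ifit2 and Cmpk2 were named after their values were seen. The median was -0.99 (camera adjusted p = 2.4e-20, and adjusted p = 0.0129 with an estimated correlation). Of the inflammatory cytokines and mediators 6 of 20 fell, namely Tnf, Il1b, Cxcl2, Cxcl3, Nos2 and Nfkbia, and 11 fell when adjusted over the list alone. Their median was -0.73 (camera adjusted p = 1.1e-18, and adjusted p = 0.116 with an estimated correlation). Slc7a11 fell to 1.35 ± 0.364 FPKM as the only member of 19 NRF2 targets past the test, and Slc25a37 fell to 4.14 ± 0.799 FPKM as the only one of 14 iron genes. Adjusted over the list alone 3 NRF2 targets fell (Slc7a11, Gclm and Gsr) and 4 iron genes fell (Slc25a37, Fbxl5, Slc11a2 and Lcn2). The medians were -0.26 and -0.28 (camera adjusted p = 0.00743 and 0.00330, and adjusted p = 0.505 and 0.150 with an estimated correlation), and the NRF2 call ended without Ta3 replicate 1 (median -0.19, adjusted p = 0.0740).

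Mitochondrially encoded genes were lower on Ta3, with 0 of 12 past the limma test and all 12 below 0. Their median was -0.43 (camera adjusted p = 0.00622, and adjusted p = 0.505 with an estimated correlation), and the call ended without Ta3 replicate 3 (median -0.38, adjusted p = 0.0907). They took 1.84 ± 0.436% of the reads on cpTi, 1.35 ± 0.131% on Ta0 and 1.00 ± 0.122% on Ta3. The exact two-sided permutation p was 0.1 for Ta3 against cpTi and also for Ta3 against Ta0, the smallest that 3 against 3 allows. Ribosomal protein genes had a median of 0.63 with 0 of 25 past the test (camera adjusted p = 0.0218, and adjusted p = 0.813 with an estimated correlation). That median turned to -0.22 without Ta3 replicate 3, and the call also ended without cpTi replicate 3 (0.22) or Ta3 replicate 1 (0.46). Integrin and actin genes had a median of 0.30 with 0 of 24 past the test (camera adjusted p = 0.0205, and adjusted p = 0.813 with an estimated correlation). The integrin call was lost without cpTi replicate 1 (0.21) or 2 (0.07) or Ta3 replicate 1 (0.26) or 2 (0.03). For this comparison the simulated unchanged groups gave a mean of 2.78 of 27 lists called with the preset correlation, and 0 with an estimated one.

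Between the glass with tantalum and the glass without it, limma called 0 of 10858 genes, with 462 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.846. Limma on rebuilt reads with voom weights also called 0, with 378 genes at an unadjusted p under 0.05. In simulated data at this size 132, 134 and 134 genes were changed by 1, 2 and 3 on the log2 scale between these groups. The same fit called 41.4%, 81.3% and 91.2% of them. With fewer changed genes these shares would be lower, since the adjustment depends on how many genes pass. They do not give the power to find a few changed genes. Among the genes fixed beforehand, Il1b stood at 1.13 ± 0.194 FPKM on Ta0 and 0.642 ± 0.326 on Ta3 (adjusted p = 0.846), and Arg1, an arginine-degrading enzyme of alternatively activated macrophages, at 576 ± 143 and 295 ± 154 FPKM (adjusted p = 0.846). Spp1, which encodes osteopontin, stood at 9963 ± 2451 and 6193 ± 3258 FPKM (adjusted p = 0.846). Tgfb1 stood at 35.6 ± 7.09 and 60.1 ± 28.1 FPKM.

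Several gene groups differed between the glasses by camera with the preset correlation, and none did with an estimated one. In 40 simulations of unchanged groups for this comparison, the preset correlation called a mean of 2.8 and up to 6 of 27 lists, the ribosomal list in 26 runs, against 5 called here. Integrin and actin genes, which serve adhesion and cell shape, were higher on Ta3 as a group, with a median of 0.38, 23 of 24 members above 0 and 0 past the limma test (camera adjusted p = 0.000158, and adjusted p = 0.747 with an estimated correlation). Fibroblast and stromal markers had a median of 0.48 over 8 tested members with 0 past the test (adjusted p = 0.0205, and adjusted p = 0.615 with an estimated correlation). Lower on Ta3 were ribosomal protein genes (median -0.82, adjusted p = 0.0107), oxidative phosphorylation genes (-0.45, adjusted p = 0.0359) and inflammatory cytokines and mediators (-0.30, adjusted p = 0.0305), with 0 members past the test in each. With an estimated correlation these were adjusted p = 0.813, 0.813 and 0.669. Without Ta3 replicate 2, the library with the lowest ribosomal protein share, the medians were 0.14 for integrins, 0.18 for ribosomal proteins, 0.07 for oxidative phosphorylation and -0.07 for the inflammatory list, and these calls ended. Calls were also lost without Ta0 replicate 1 (ribosomal -0.21, oxidative phosphorylation -0.13, inflammatory -0.18), without Ta0 replicate 3 (inflammatory -0.33), without Ta3 replicate 1 (oxidative phosphorylation -0.54, fibroblast markers 0.43) and without Ta3 replicate 3 (fibroblast markers 0.62). The oxidative phosphorylation and inflammatory medians were 0.003 and 0.06 when libraries were rescaled to a common FPKM total, where the median of all genes was 0.35, against -0.04 as deposited.

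**Figure D3:**
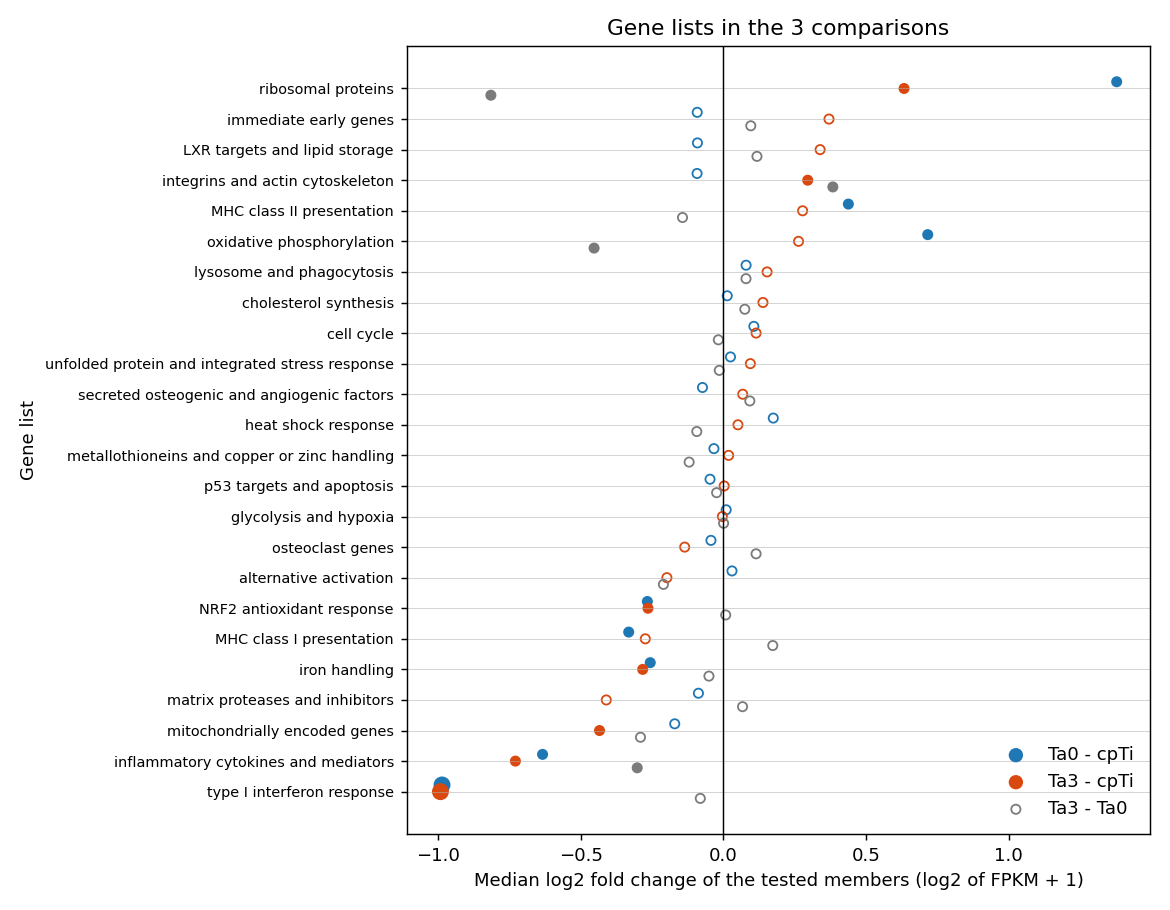
Each point is the median log2 fold change of a gene list in 1 of the 3 comparisons, on the log2(FPKM + 1) scale, filled where camera passed with the preset correlation and large where it also passed with an estimated one. The type I interferon list stands at -0.99 on both glasses against cpTi and at -0.08 between the glasses.

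Of the 46 genes called on Ta0 and the 52 called on Ta3, 35 were called on both, 3 higher (Cdkn1c, Cd5l and Lsp1) and 32 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.185 lower genes and 0.00138 higher ones, but these lists are not independent, since they share the cpTi libraries. Across all genes, which are not independent replicates, 66.9% had the same sign on both glasses, against a mean of 66.8% in 100 simulations of unchanged groups against the same cpTi libraries. The fold changes had a correlation across genes of 0.645, inside the simulated range of -0.698 to 0.984, and a covariance of 0.125, which is above the simulated mean of 0.0652 by less than the simulated SD of 0.0998. The simulations shared 0 genes, but that count says little, since a shared gene needs a call in both comparisons. Calls were rare in the 40 simulated runs with unchanged groups, where limma called a gene in 0, 5 and 3 runs for the 3 comparisons. The 3 cpTi libraries are too few to be split between the comparisons, so part of the overlap may come from the shared controls. The overlap was 7 genes without Ta0 replicate 2, 8 without cpTi replicate 1, 9 without cpTi replicate 2 or Ta3 replicate 1, 10 without Ta0 replicate 1 or 3, 12 without cpTi replicate 3, 20 without Ta3 replicate 2 and 25 without Ta3 replicate 3.

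Several genes fixed beforehand did not pass against cpTi. Metal-responsive Mt1, a metallothionein that binds zinc and copper, stood at 122 ± 33.2 FPKM on cpTi, 226 ± 162 on Ta0 and 202 ± 124 on Ta3 (adjusted p = 0.750 and 0.949), with 412 FPKM in Ta0 replicate 1 and 341 in Ta3 replicate 3. Mt2 stood at 0.301 ± 0.0146, 1.24 ± 1.56 and 1.82 ± 1.72 FPKM, and the zinc exporter gene Slc30a1 at 6.87 ± 0.603, 7.54 ± 0.767 and 8.86 ± 2.65 FPKM. The heme-degrading enzyme Hmox1 stood at 315 ± 58.4, 211 ± 15.3 and 231 ± 38.5 FPKM. Arg1 stood at 822 ± 303, 576 ± 143 and 295 ± 154 FPKM (adjusted p = 0.772 and 0.510), Mrc1 at 10.6 ± 4.42, 10.3 ± 0.723 and 12.2 ± 4.40, and the costimulatory gene Cd86 at 10.5 ± 2.54, 6.96 ± 1.34 and 5.94 ± 2.78. Among bone-related genes, Spp1 stood at 4960 ± 1067 FPKM on cpTi (adjusted p = 0.750 and 0.979), Acp5 at 97.7 ± 26.6, 59.3 ± 6.04 and 53.3 ± 12.3, Bmp2 at 2.19 ± 0.799, 1.24 ± 0.165 and 1.28 ± 1.12, and Osm at 4.03 ± 0.424, 2.83 ± 0.880 and 2.56 ± 0.484 FPKM. Tgfb1 stood at 41.2 ± 15.2 FPKM on cpTi, and Vegfa at 20.6 ± 6.10, 15.4 ± 3.93 and 17.7 ± 8.02 FPKM. Il6 and Il10 were below the expression filter and not tested. In replicates 1, 2 and 3 Il6 stood at 0.551, 0.899 and 0.188 FPKM on cpTi, 0, 0.148 and 0.101 on Ta0 and 0.0669, 0.134 and 0 on Ta3, and Il10 at 0.298, 0.324 and 0.0348 on cpTi, 0, 0.549 and 0.280 on Ta0 and 0.289, 0.212 and 3.59 on Ta3.

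The remaining lists gave no call by camera. Among them fry passed matrix proteases and inhibitors on Ta0 and on Ta3 against cpTi (fry adjusted p = 0.0325 and 0.0156). Of the lists called by camera, fry passed the interferon list on Ta0 and Ta3 against cpTi (fry adjusted p = 0.000843 and 0.000809). It also passed the inflammatory (0.0156 and 0.0080), NRF2 (0.0272 and 0.0325) and iron lists (0.00269 on each). Fry passed no other called list, with 0.57 for ribosomal proteins on Ta0 and 0.66 for integrins between the glasses. It was not run on the simulated unchanged groups. Against cpTi, the metallothionein and copper or zinc list had medians of -0.03 on Ta0 and 0.02 on Ta3 with 0 of 17 members past the test (adjusted p = 0.717 for each), and Slc31a1, the copper importer gene, fell on Ta3 when adjusted over the list alone. For alternative activation the medians were 0.03 and -0.20 (adjusted p = 0.993 and 0.717), with Pparg as the only one of 15 members to rise on Ta0. Of 14 matrix proteases and inhibitors Mmp8, a collagenase, fell on both glasses, and the medians were -0.09 and -0.41 (adjusted p = 0.116 and 0.0985). Mmp8, named after its values were seen, stood at 86.6 ± 13 FPKM on cpTi, 27.7 ± 6.56 on Ta0 and 19.2 ± 1.5 on Ta3. Osteoclast genes had medians of -0.04 and -0.14 (adjusted p = 0.370 and 0.852), secreted osteogenic and angiogenic factors -0.07 and 0.07 (0.906 and 0.445), lysosome and phagocytosis genes 0.08 and 0.15 (0.889 and 0.419), and LXR targets and lipid storage genes -0.09 and 0.34 (0.940 and 0.0775). For cholesterol synthesis they were 0.01 and 0.14 (0.902 and 0.0540), for heat shock 0.18 and 0.05 (0.0826 and 0.742), and for the unfolded protein and integrated stress response 0.02 and 0.09 (0.550 and 0.194). Cell cycle genes had 0.11 and 0.11 (0.22 and 0.194), p53 targets and apoptosis genes -0.05 and 0.003 (0.717 and 0.486), immediate early genes -0.09 and 0.37 (0.953 and 0.243), and glycolysis and hypoxia genes 0.01 and -0.004 (0.878 and 0.717). Vegfb stood at 15.2 ± 2.46 FPKM on cpTi, 17.2 ± 1.70 on Ta0 and 31.5 ± 5.79 on Ta3. Over all genes limma called it neither on Ta3 against cpTi (adjusted p = 0.1003) nor on Ta3 against Ta0 (adjusted p = 0.8457). Vegfb passed as higher on Ta3 in both comparisons only when adjusted over the list of secreted factors alone. That adjustment does not cover the other lists. Some lists called in 1 comparison with cpTi missed the threshold in the other. On Ta3 these were MHC class I genes (-0.27, adjusted p = 0.0913), MHC class II genes (0.28, adjusted p = 0.0913) and oxidative phosphorylation genes (0.26, adjusted p = 0.124), and on Ta0 integrin and actin genes (-0.09, adjusted p = 0.486) and mitochondrially encoded genes (-0.17, adjusted p = 0.529).

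Between the glasses the uncalled lists had medians from -0.31, for monocyte markers, to 0.17, for MHC class I genes. The nearest to the threshold were mitochondrially encoded genes (-0.29, adjusted p = 0.0572), cholesterol synthesis genes (0.08, adjusted p = 0.0674) and LXR targets (0.12, adjusted p = 0.0775). The median, the mean and the direction of the camera test did not share a sign in several uncalled lists. On Ta0 against cpTi these were alternative activation, the metallothionein list, LXR targets, immediate early genes, secreted factors and macrophage markers, and on Ta3 against cpTi the metallothionein list and p53 targets. Between the glasses they were NRF2 targets, the unfolded protein response, glycolysis, cell cycle, iron handling, matrix proteases and macrophage markers.

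Cell type markers did not set the materials apart as lists against cpTi. Macrophage markers had medians of 0.15 on Ta0 and -0.06 on Ta3 (adjusted p = 0.878 and 0.889), and adjusted over the list alone Adgre1 fell and Cd300a rose on both glasses. Adgre1, which encodes the F4/80 antigen, stood at 157 ± 7.67, 89.1 ± 9.98 and 87.9 ± 8.14 FPKM. Monocyte markers had medians of -0.22 and -0.33 (adjusted p = 0.717 and 0.311), with Ly6c2 and F13a1 lower on Ta3 when adjusted over the list alone, and fibroblast and stromal markers -0.16 and 0.32 (adjusted p = 0.561 and 0.177). Lists with fewer than 5 tested members were not tested as lists. Their highest group means were 200 FPKM for S100a8 among neutrophil markers, 98.4 for Il7r among T and NK cell markers, 13.3 for Fscn1 among dendritic cell markers, 9.78 for Hbb-bs among erythroid markers, 5.89 for Ighm among B cell markers, 3.69 for Cpa3 among mast cell markers and 0.566 for Kdr among endothelial markers. S100a8 stood at 144 ± 104 FPKM on cpTi, 200 ± 148 on Ta0 and 161 ± 186 on Ta3.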

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

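The tests on gene length, rebuilt reads, FPKM scaled by the sum of all rebuilt reads and 7 libraries were chosen after seeing the data, and the other alternatives were planned. Of 32 calls of named genes, 6 held under every alternative (Acod1 and Cxcl2 in both comparisons with cpTi, Cxcl3 on Ta0 and Il1b on Ta3), 10 held without each single library, and 0 reversed. Of 20 list calls, the interferon calls of both glasses held under every alternative, and 9 held without each single library. Among 2262 list values 2094 stayed on their side of the threshold, 68 lost a call, 92 gained one and 8 reversed, and among 1986 gene values the counts were 1692, 259, 35 and 0. Of those that stayed, 140 list values and 67 gene values changed direction with no call in either fit. Most results in these totals had no call in the main fit, so the totals say little about how firm the calls are. The median-ratio setting repeats the scaling that the deposited FPKM carry, and all its 81 list values and 74 gene values stayed. The direction of a list is the one camera gives, against the other genes, so a call can be kept while the median turns. Rescaled to a common FPKM total, this held for the inflammatory (0.06) and oxidative phosphorylation (0.003) lists on Ta3 against Ta0. Every gene called against cpTi kept its sign in each alternative in which it was tested. The median log2 fold change of all genes was -0.001, 0.02 and -0.04 for Ta0 against cpTi, Ta3 against cpTi and Ta3 against Ta0. It was -0.53, -0.11 and 0.35 when rescaled to a common FPKM total, -0.46, -0.26 and 0.12 with that rescaling without mitochondrial, ribosomal protein and top genes, and -0.29, -0.15 and 0.08 when scaled by the sum of all rebuilt reads.

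For Ta0 against cpTi, Ta3 against cpTi and their overlap, where 46, 52 and 35 genes passed, the counts were 27, 29 and 22 with a pseudocount of 0.1, 28, 21 and 20 without the filter, 11, 9 and 9 rescaled to a common FPKM total, 15, 18 and 14 with that rescaling without mitochondrial, ribosomal protein and top genes, and 11, 10 and 9 at an adjusted p under 0.01, a lower threshold that can only remove genes. They were 246, 583 and 212 with the length slope as a covariate, 78, 88 and 62 with the length lowess, 93, 99 and 70 with length and GC, 22, 32 and 21 scaled by the sum of all rebuilt reads, and 20, 18 and 12 with 7 libraries, which leave fewer residual degrees of freedom. Ta3 against cpTi gave 31 genes at a filter of 5 FPKM, 7 with only the 6 libraries compared and 31 on rebuilt reads with voom weights. Sample quality weights gave 4684, 9022 and 3213, and 5876 genes for Ta3 against Ta0. That estimate did not converge, with weights from 0.0668 for Ta3 replicate 3 to 318 for Ta3 replicate 1, so it rests on about 1 library per group. Ta3 against Ta0 gave 0 genes in limma in each other alternative, against 462 at an unadjusted p under 0.05 with all libraries and 378 with voom weights. Leaving out 1 library gave 7 to 84 genes for Ta0 against cpTi, 8 to 30 for Ta3 against cpTi and 7 to 25 for the overlap. Except where stated, the cause was not tested.

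The correlations between libraries showed no pairing of the samples by replicate number, but they cannot exclude one. The first principal component held 72.0% of the variance and could hide a smaller shared effect. Of 9 pairs with the same number 4 correlated over 0.1, from -0.821 to 0.848, and 3 of 9 libraries correlated best with their own number. A block by number gave 4, 4 and 3 genes and leaves fewer residual degrees of freedom.

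Reversed list medians were -0.49 for lysosome and phagocytosis on Ta0 with quantiles, and 0.24 for integrins on Ta0, 0.035 for oxidative phosphorylation and 0.074 for ribosomal proteins on Ta3 against Ta0 with the length slope. Ribosomal proteins on Ta3 against cpTi went to -0.22 without Ta3 replicate 3 and with 7 libraries. Leaving out 1 library gave -0.22 to 1.58 for that list, -1.67 to 0.18 for ribosomal proteins and -1.14 to 0.068 for oxidative phosphorylation on Ta3 against Ta0, with both highest values without Ta3 replicate 2. The cause was not tested.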

Other observations

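The tests on 7 libraries, on neutrophil markers, with the length slope as a covariate, the separate length tests of ribosomal proteins and oxidative phosphorylation, and the splits of the inflammatory and interferon medians were chosen only after the result was seen. The comparison of both glasses together with cpTi is outside the planned design and was added after the data were seen, with its count of genes over other splits set before that count was seen. The count of shared genes over all 840 splits was added after the 100 drawn splits were seen, and the list calls over splits with the adjustment over 81 tests after those adjusted within a comparison. The other length tests and the other counts over splits were set before their results were seen.

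The genes in this paragraph were chosen after their values were seen, and the first 5 were called lower on both glasses. Ptges, which makes prostaglandin E2, stood at 31.3 ± 7.49 FPKM on cpTi, 3.5 ± 0.247 on Ta0 and 3.32 ± 0.799 on Ta3 (n = 3). The toll-like receptor gene Tlr2 stood at 32.4 ± 1.71, 8.37 ± 0.863 and 11.2 ± 3.33 FPKM. Lox, a collagen cross-linking enzyme, stood at 11.3 ± 2.03, 2.47 ± 0.200 and 2.85 ± 1.26 FPKM, Tgfbi, a matrix protein, at 31.5 ± 4.65, 11.1 ± 0.107 and 11.3 ± 1.62, and Inhba, the activin A subunit, at 4.84 ± 0.562, 0.908 ± 0.244 and 0.856 ± 0.0636. Clec4e, a receptor for mycobacterial glycolipid, was called on Ta3 only, at 355 ± 167 FPKM on cpTi, 72.0 ± 19.1 on Ta0 and 49.1 ± 23.3 on Ta3, and its difference between the glasses did not pass.

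For the inflammatory and interferon lists, called lower on both glasses than on cpTi with the preset correlation (with an estimated correlation adjusted p = 0.150 on Ta0 and 0.116 on Ta3 for the inflammatory list, which loses its calls, and 0.0129 on both for the interferon list), genes matched to the members on length and level had medians above 0 in all 4 list comparisons, with 0.022 (-0.094 to 0.155) for the interferon list on Ta0, which argues against length bias. With 7 libraries each list kept at least 93.1% of its median, which argues against the libraries with few single-read genes as the main cause. With the length slope as a covariate each list kept at least 89.1%. That argues against a component between libraries that follows the length slope as the main cause. Other components that vary between libraries of the same material were not tested. Neutrophil RNA in the cpTi libraries cannot be told apart, since the 4 tested markers differed by 0.91 on Ta0 and -0.13 on Ta3 with an SE of 0.84 each. Of 84 choices of 3 libraries as the reference, 1, the real one, gave a mean of the list medians as far from 0 (-0.79, against 0.72 for the highest other), but the lists were picked because they were lower, so this does not exclude chance. A response to the material may underlie the lower lists, a hypothesis that stays beside the open neutrophil source and the untested components between libraries. Without a culture on another surface, such a response could lie with the glasses or with cpTi.

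Camera called the ribosomal protein and oxidative phosphorylation lists higher on Ta0 than on cpTi only with the preset correlation (adjusted p = 0.698 and 0.733 with an estimated correlation), with 0 of 25 members past limma in each, and it called the ribosomal list in 30 of 40 unchanged runs. Matched genes had a median of 0.45 (0.28 to 0.66) for ribosomal proteins, short of the list's 1.38. This argues against bias on the deposited gene length as the main cause. All matched tests used that length, with a median of 2431 bases for the ribosomal members and 2385 for their matches. A bias on the length of the transcripts present in the cells was not tested. For oxidative phosphorylation the matched median was 0.27 (0.09 to 0.61), which leaves length open there. With the length slope as a covariate the lists kept at most 12.7% of their medians, and the ribosomal call held (camera adjusted p = 0.00948). A component that varies between libraries of the same material may account for most of both, but this test cannot decide it. The slope ran with the ribosomal protein share over the libraries, and its mean was -0.094 on Ta0 and 0.070 on cpTi. Adjusting for it can therefore remove the shift of these lists whatever the cause. The length lowess kept 87.0% and 64.9%. A difference due to the material stays untested beside that component.

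Camera called the integrin and actin list higher on Ta3 than on Ta0 only with the preset correlation (adjusted p = 0.747 with an estimated correlation), with 0 of 24 members past limma. Matched genes had a median of 0.014 (-0.12 to 0.17) against the list's 0.38, which argues against length bias. With the length slope as a covariate 33.7% of the median was kept, at 0.13, and the call ended (adjusted p = 0.0733), so the component between libraries may account for much of it. The slope also differed in mean, at 0.023 on Ta3 and -0.094 on Ta0, so this does not separate the component from the glass. With 7 libraries the median was 0.57. The tantalum content of the glass stays an untested alternative.

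Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For Ta0 against cpTi 1 split gave as many genes (46, highest other 1) and 2 gave as many list calls adjusted over the 27 lists of the comparison (8, highest other 9). For Ta3 against cpTi 2 splits gave as many genes (52, highest other 794) and 1 as many list calls with that adjustment (8, highest other 7), but adjusted over 81 tests, as in the Results, 2 splits gave as many (7, highest other 7). The split with 794 genes, which puts cpTi replicates 1 and 2 with Ta3 replicate 3, points to a structure of the libraries. For Ta3 against Ta0 all 10 splits gave 0 genes in limma, which called 0 with 462 genes at an unadjusted p under 0.05 (378 with voom weights), and 1 split gave as many list calls (5, highest other 3) with either adjustment. Of 100 drawn splits of the 9 libraries 1, the real one, gave as many shared genes (35, highest other 2). Of all 840 splits 4 gave as many, the real one, 2 that keep the cpTi libraries together as the reference (36 and 57) and 1 that does not (316). Only 23 of the 840 called a gene in both of their comparisons, so a low shared count says little, and chance is not taken as excluded for the overlap. Both glasses against cpTi gave 100 genes, and 3 of 84 splits gave as many, a share under 0.05. The other 2 of these gave 2103 and 2547, many times the real count, which points to a structure of the libraries, so chance is not taken as excluded for that count.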
